A study of Homo sapiens with 2 samples.

How the data were processed

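RNA was sequenced from MCF7 cells treated for 18 h with DMSO or the extract CANN14. Per the labels, each of the 2 deposited samples stands for 3 replicates, total RNA was isolated with TRI reagent, and libraries were made with the TruSeq RNA kit v2, which selects poly(A) RNA and does not mark strand. The submitters' processing notes name FastQC 0.11.5, Trim Galore, cutadapt 1.10, TopHat2 2.1.0, Bowtie2 2.2.6, HTSeq 0.11.2, DESeq2 1.24.0 and the GRCh38 build, without the role or settings of each. The annotation release and the strand setting of the counting are not given in the sources used here. Gene starts and ends in the table matched those of GENCODE release 29 in 96.3% of rows, and exonic lengths were taken from that release.

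The authors deposited a single table of 58174 genes. Per the file headers it holds, for each gene, 3 normalized counts of DMSO (columns numbered 1 to 3) and 3 of CANN14 (numbered 4 to 6). It also holds the authors' mean signal over all libraries, their deposited log2 fold change of CANN14 over DMSO, and their deposited p-value and adjusted p-value. Of these genes, 13791 were at 0 in every library, 22853 were marked by the authors as low count and 21530 had an authors' adjusted p-value. The deposited values come from reads already normalized for library size by the authors. Per library, every normalized count was a whole multiple of what 1 read was worth, within 0.01 of a whole read for 100% of values, and the means of the recovered values matched the authors' mean signal to a relative gap of 7.3e-15. Library sizes in the report are the sums of these recovered reads.

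The design fixed before the data were examined named a count test. Should the table hold normalized counts, limma on log2 values was to be the main test. The count test was then to be run on recovered reads where these came out whole. The table holds normalized counts and the reads came out whole, but the count test was not run. The main test was limma-trend 3.58.1 in R 4.3.3 on log2(normalized count + 1), CANN14 against DMSO, with no covariate. Genes with at least 10 normalized counts in at least 3 libraries were tested. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on this log2 scale, which understates the change of low genes. Errors of log2 changes are limma's standard errors, and errors of normalized counts are SDs over 3 replicates. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Exact permutation of 3 against 3 libraries cannot go below 0.1, so the calls rest on limma's model across genes.

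The 34 gene lists were fixed before the data were examined and hold 736 symbols, of which 2 matched no row. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists, with camera at an estimated correlation and fry as alternatives. A list member counts as measured when it passed the filter on low counts. The genes named in the report follow a rule also fixed then. They are the 12 largest rises and 12 largest falls among called genes with a mean of at least 50 normalized counts, replicates that do not overlap and a symbol that is not a clone name. Added to these are the up to 4 members of each list with the smallest adjusted p, and ESR1, CYP1A1, DDIT3, CHAC1, HMGCS1, CDKN1A, MKI67 and GREB1. Lists in the closing observations were chosen after the values were seen.

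The alternatives fixed before the data were examined were upper-quartile scaling, total-count scaling on log2(CPM + 1), no filter, a mean of at least 50 normalized counts, pseudocounts of 0.1 and 8, an adjusted p under 0.01, leaving out each replicate, and the authors' deposited calls. limma's voom on the recovered reads, both of these scalings for the gene lists, and total counts scaled to the mean library total, were added afterwards. Tests ran first on simulated data, with counts drawn for 19237 genes passing the filter from the real means and library sizes. All genes shared a dispersion of 0.0021, and only 50 genes were changed at each fold. For CANN14 against DMSO, limma-trend recovered 26 of 50 genes changed 1.25-fold, 38 of 50 at 1.5-fold, 44 of 50 at 2-fold and 47 of 50 at 4-fold, all in the right direction, with 8 false calls. Camera called the list of 25 changed genes and 0 of 33 unchanged lists. The simulated genes were drawn independently, whereas estimated correlations within the real lists reached 0.800. The simulation thus cannot show how often camera calls unchanged lists whose genes move together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.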

Results

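RNA was sequenced from MCF7 cells, an established human breast cancer line that expresses the oestrogen receptor. The cells had been treated for 18 h with the Cannabis extract CANN14 or with its DMSO vehicle, in medium without phenol red, a dye with weak oestrogenic activity. Each group had 3 replicates. The deposited table gave a normalized count per gene and replicate for 58174 genes. The values were whole multiples of what 1 read was worth in each library, so library sizes could be read back. DMSO replicates 1 to 3 held 34006932, 39177023 and 37159547 reads assigned to genes, and CANN14 replicates 4 to 6 held 36445552, 40576903 and 26193119. Between 31475 and 38106 genes had at least 1 read in a library. DMSO replicate 2 had the most, with 4037 genes detected in no other library, against 562 to 763 in each of the other 5. These 4037 genes held 5945 of its reads. The 10 most abundant genes took 11.0% to 12.2% of the reads of each library.

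The comparison of CANN14 with DMSO asked which genes the extract raised or lowered within 18 h. Genes of stress responses were among the largest rises, and the oestrogen receptor gene fell. HMOX1 (ENSG00000100292, GRCh38 chromosome 22, 35380361 to 35394214), which encodes the haem-degrading enzyme haem oxygenase, rose from 520 ± 48.4 to 4836 ± 898 normalized counts (SD, n = 3). Its log2 change was 3.20 ± 0.09 (SE), with an adjusted p of 1.19e-17 in limma-trend. DDIT3 (chromosome 12, 57516588 to 57520517), the transcription factor CHOP of the integrated stress response, rose from 490 ± 7.26 to 3366 ± 868, a log2 change of 2.75 ± 0.10. SLC3A2 (chromosome 11, 62856102 to 62888875), the heavy chain of several amino acid transporters, rose from 5637 ± 224 to 29574 ± 4049, a log2 change of 2.38 ± 0.07. ESR1 (chromosome 6, 151656691 to 152129619), the gene of oestrogen receptor alpha, fell from 9916 ± 251 to 5859 ± 337, a log2 change of -0.76 ± 0.06 (adjusted p = 1.35e-10, limma).

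Among 19773 tested genes, limma-trend called 9036 at an adjusted p under 0.05, of which 4745 rose and 4291 fell. Of these, 1049 changed at least 2-fold on the log2(normalized count + 1) scale, 731 upward and 318 downward. The 3 CANN14 values lay entirely on one side of the 3 DMSO values in 8665 of the called genes, or 95.9%, and in 54.5% of all tested genes, where chance gives 10%. Total-count scaling on log2(CPM + 1) gave 3917 genes up and 5525 down, with a median log2 change of all genes of -0.05. That alternative changed the scaling and the unit that the pseudocount is added to. With total counts scaled to the mean library total, added after the data were seen to keep the unit, 3891 rose and 5464 fell (median -0.08) and 1065 changed at least 2-fold. The 2-fold count was 285 on log2(CPM + 1), 460 with a mean of at least 50 normalized counts, 629 with a pseudocount of 8 and 504 in the authors' deposited table. The last rests on the authors' own log2 changes.

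**Figure D1:**
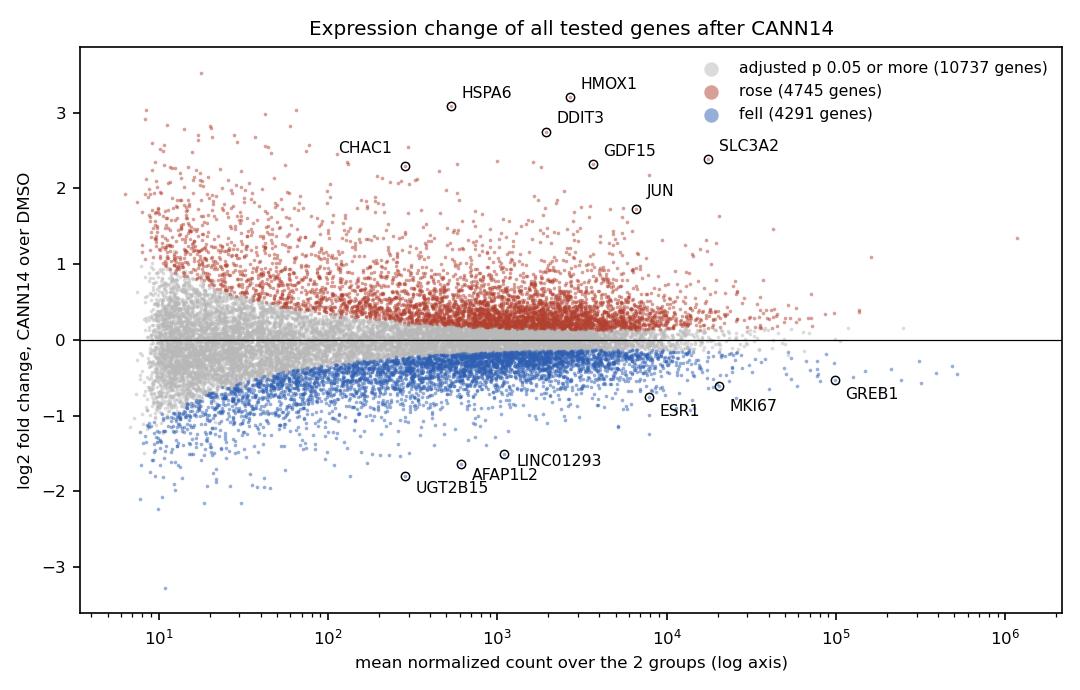
Log2 fold change of CANN14 over DMSO (vertical axis) against the mean normalized count over both groups (horizontal log axis) for each of 19773 tested genes. Red points are the 4745 genes that rose, blue points the 4291 that fell and grey points those not called. Circles mark genes named in the text, such as HMOX1 at 3.20 and UGT2B15 at -1.80.

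The other genes among the 12 largest rises covered several functions. HSPA6 (chromosome 1, 161524540 to 161526910), a heat-inducible chaperone of the HSP70 family, rose from 108 ± 14.5 to 959 ± 354 normalized counts, although close copies can share its reads. ATF3, a stress-induced transcription factor, rose from 317 ± 26.1 to 1666 ± 457, and BHLHA15, a transcription factor of secretory cells, from 12.7 ± 2.87 to 116 ± 48.6. The GTP-binding protein gene GEM rose by 2.55 ± 0.15 on the log2 scale, and the microtubule-associated protein gene MAP1B by 2.35 ± 0.12. SCN4A, a voltage-gated sodium channel gene, rose by 2.82 ± 0.28, and C11orf96 by 2.49 ± 0.22. The 2 remaining rises are uncertain as separate genes. ASNSP1 (2.57 ± 0.22) is a pseudogene of asparagine synthetase and may share its reads. SLC7A11-AS1 (2.45 ± 0.18) overlaps SLC7A11, and the library kit does not mark strand.

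By the same rule, each of the 12 largest falls was smaller than each of the 12 largest rises. UGT2B15 (chromosome 4, 68646630 to 68670628), which encodes an enzyme that glucuronidates steroids, fell from 444 ± 18.5 to 128 ± 14.6 normalized counts, a log2 change of -1.80 ± 0.10. It has near-identical paralogs, so its level is uncertain. AFAP1L2 (chromosome 10, 114294824 to 114404756), an adaptor protein gene linked to Src signalling, fell from 922 ± 41.4 to 298 ± 43.6, and CLCA2, a regulator of chloride channels, from 258 ± 14.3 to 83.3 ± 8.61. GNAO1, a G protein alpha subunit, fell by 1.53 ± 0.10 on the log2 scale, PLXNA4, a semaphorin receptor, by 1.52 ± 0.11, and ITGB6, an integrin subunit, by 1.51 ± 0.14. The ion channel subunit gene GABRP fell by 1.57 ± 0.17, ART4 by 1.72 ± 0.21, CLEC3A by 1.66 ± 0.16, and METTL7A fell by 1.49 ± 0.11. Of the long intergenic non-coding RNAs, LINC01522 fell by 1.80 ± 0.15 and LINC01293 by 1.50 ± 0.08.

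**Figure D2:**
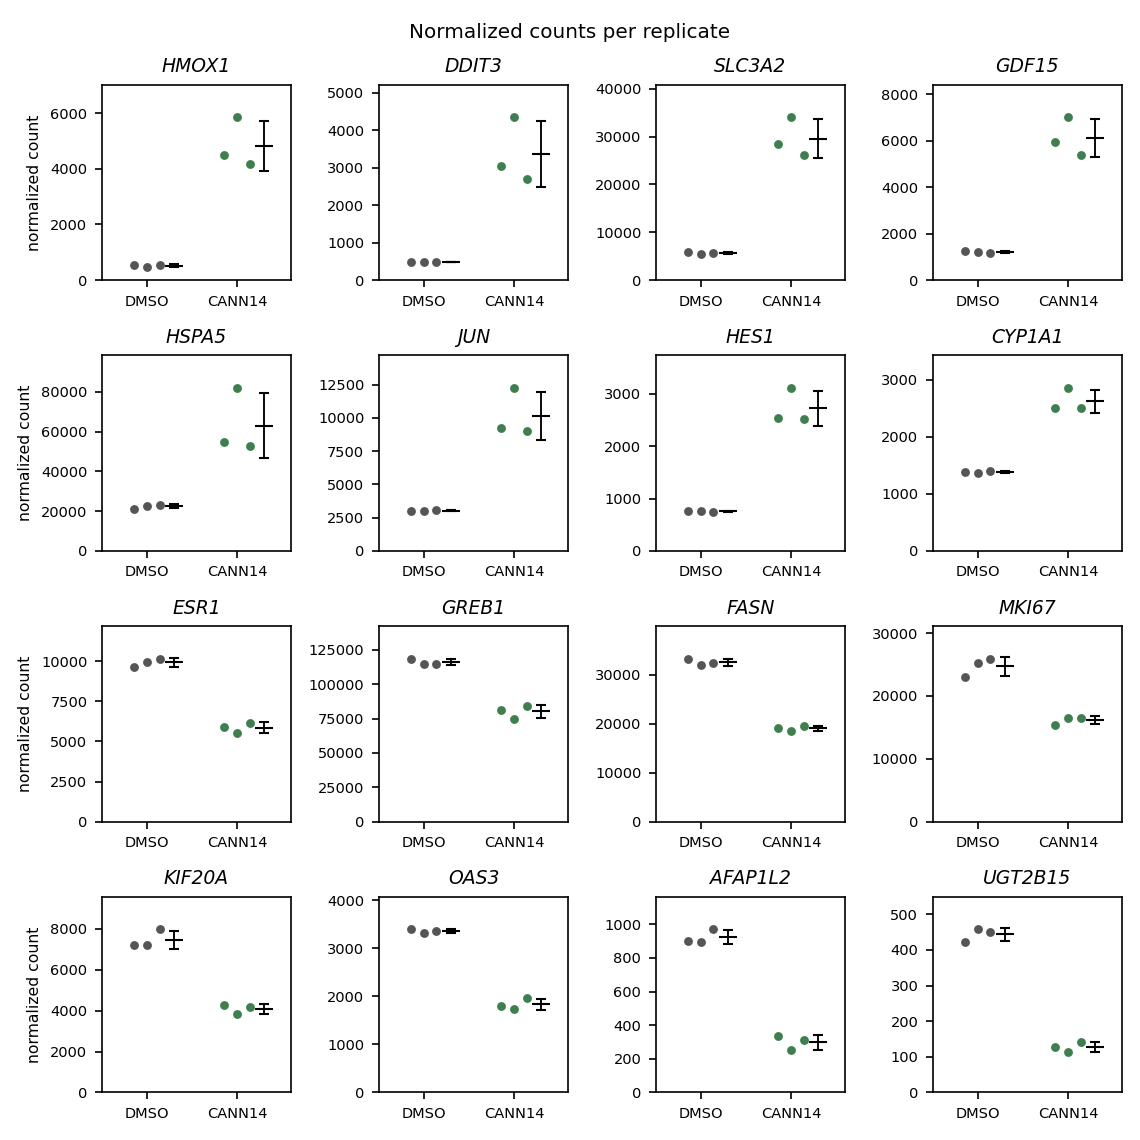
Normalized counts (vertical axes, linear from 0) of 16 named genes in each DMSO (grey) and CANN14 (green) replicate, with the mean and SD of each group of 3 beside the points. All 3 CANN14 values lie above all DMSO values for HMOX1 to CYP1A1 and below them for ESR1 to UGT2B15, and for HSPA5 the values of CANN14 replicates 4, 5 and 6 are 54525, 81944 and 52560.

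Of 34 gene lists fixed before the data were examined, 19 differed from the other genes in limma's camera test with a preset correlation of 0.01, 14 upward and 5 downward. None of these 19 calls held with a correlation estimated from the 6 libraries, whose adjusted p is given beside each list. Member counts are of genes past an adjusted p of 0.05 over all tested genes. The counts adjusted over the list alone were the same unless given. Single members that moved against the rest of a list were named after their values were seen. The lists shared 21 genes.

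The ATF4 list, targets of the transcription factor that drives amino acid synthesis and import under stress, had the smallest p. Of its 31 measured members 28 rose and 0 fell, with a median log2 change of 1.25 (camera adjusted p = 2.89e-15; adjusted p = 0.293 with an estimated correlation). Beside DDIT3 and SLC3A2, GDF15, a secreted stress cytokine, rose from 1219 ± 39.2 to 6125 ± 826 normalized counts, and the cystine transporter gene SLC7A11 from 616 ± 44.4 to 3020 ± 583. CHAC1, which encodes a glutathione-degrading enzyme, rose by 2.30 ± 0.13. ER chaperones and unfolded protein response genes rose in 20 of 22 cases with 0 falling (median 0.56, camera adjusted p = 2.19e-07; adjusted p = 0.420 with an estimated correlation). HSPA5, the ER chaperone BiP, rose from 22369 ± 998 to 63010 ± 16427. Its cochaperone gene DNAJB9 rose by 1.97 ± 0.10, HERPUD1, a component of ER-associated degradation, by 1.76 ± 0.09, and the ER stress sensor gene ERN1 by 1.44 ± 0.08. CANN14 replicate 5 had the highest value of the 3 in each of these genes. Without it, the median of the ATF4 list was 1.17 and that of the ER list 0.45, with 28 and 19 members rising.

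NRF2 targets, antioxidant and detoxifying genes, rose in 19 of 25 cases (21 adjusted over the list alone), and TXN fell (median 0.64, camera adjusted p = 3.57e-09; adjusted p = 0.293 with an estimated correlation). HMOX1 and SLC7A11 belong to this list, as do OSGIN1, which rose by 1.81 ± 0.08, and the thioredoxin reductase gene TXNRD1, which rose by 1.32 ± 0.07. All 4 measured genes of the metallothionein list rose, with a median of 0.82 (camera adjusted p = 0.00714; adjusted p = 0.293 with an estimated correlation). They were the metallothioneins MT1X (1.31 ± 0.12), MT1F (0.96 ± 0.13) and MT2A (0.33 ± 0.06), which are similar in sequence, and the zinc exporter SLC30A1 (0.67 ± 0.07). Of 16 heat shock genes 10 rose and 2, BAG3 and FKBP4, fell (median 0.32, camera adjusted p = 0.0138; adjusted p = 0.528 with an estimated correlation). DNAJB1 rose by 1.02 ± 0.08 and HSPA1B, nearly identical to HSPA1A, by 0.92 ± 0.08, while the cochaperone gene BAG3 fell by 0.54 ± 0.05. Genes of autophagy and the lysosome rose in 21 of 29 cases (22 adjusted over the list alone) and fell in 2, GLA and BECN1 (median 0.29, camera adjusted p = 3.15e-05; adjusted p = 0.293 with an estimated correlation). The autophagy receptor gene SQSTM1 rose from 9846 ± 40.3 to 30816 ± 4796, MAP1LC3B by 0.95 ± 0.08 and FLCN by 0.91 ± 0.06 on the log2 scale, whereas the lysosomal galactosidase gene GLA fell by 0.97 ± 0.06.

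Immediate early genes and feedback genes of MAP kinase signalling rose in 22 of 23 cases with 0 falling (median 1.25, camera adjusted p = 1.22e-11; adjusted p = 0.293 with an estimated correlation). The AP-1 subunit genes JUN, JUNB and FOSB rose by 1.73 ± 0.08, 1.33 ± 0.06 and 1.47 ± 0.08, and IER3 by 1.25 ± 0.06. In the NF-kB list 14 of 15 measured genes rose and 0 fell (median 1.35, camera adjusted p = 3.00e-07; adjusted p = 0.293 with an estimated correlation). Without CANN14 replicate 4, and likewise without replicate 5, 13 were measured and 12 rose, while 15 stayed measured whichever DMSO replicate was left out. Some members thus passed the filter only through the CANN14 libraries, which favours rises. The median was 0.64 with total-count scaling on log2(CPM + 1), 1.29 with total counts scaled to the mean library total, and 1.13 over the 11 members with a mean of at least 50 normalized counts. They included the adhesion molecule gene ICAM1 (1.89 ± 0.07), the NF-kB inhibitors TNFAIP3 (1.38 ± 0.06) and NFKBIA (1.13 ± 0.06), and the subunit RELB (1.36 ± 0.08). Of 17 Notch pathway genes 12 rose and NOTCH2 fell (median 0.48, camera adjusted p = 2.00e-04; adjusted p = 0.293 with an estimated correlation). The Notch targets HES1 and NRARP rose by 1.84 ± 0.07 and 1.08 ± 0.08, the receptor gene NOTCH1 by 0.56 ± 0.06 and the protease gene FURIN by 0.92 ± 0.07. Hypoxia genes rose in 10 of 17 cases with 0 falling (median 0.28, camera adjusted p = 0.00122; adjusted p = 0.293 with an estimated correlation), among them the angiogenic factor VEGFA (1.74 ± 0.07), ANGPTL4 (1.35 ± 0.14), NDRG1 (0.89 ± 0.07) and the histone demethylase gene KDM3A (0.61 ± 0.06). Genes of TGF-beta signalling and epithelial-mesenchymal transition rose in 12 of 21 cases. TGFB2 and ACTA2 fell, 3 falling when adjusted over the list alone (median 0.36, camera adjusted p = 0.00386; adjusted p = 0.293 with an estimated correlation). SNAI1, a repressor of E-cadherin, rose by 1.27 ± 0.08, and TGFBI, ITGA5 and CYR61 rose by 0.87 ± 0.08, 0.87 ± 0.08 and 0.86 ± 0.10.

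Aryl hydrocarbon receptor targets rose in 6 of 12 cases (7 adjusted over the list alone), and PPP1R3C fell (median 0.34, camera adjusted p = 0.0138; adjusted p = 0.293 with an estimated correlation). With total-count scaling on log2(CPM + 1) 5 of these targets rose and the median was 0.20. CYP1A1 (chromosome 15, 74719542 to 74725610), the most used readout of this receptor, rose from 1388 ± 19.9 to 2628 ± 202 normalized counts, a log2 change of 0.92 ± 0.06. NFE2L2, the gene of NRF2, rose by 0.63 ± 0.06, and the amino acid transporter gene SLC7A5 from 12112 ± 319 to 24213 ± 2052 normalized counts. Ribosomal protein genes rose by small amounts in 21 of 30 cases (22 adjusted over the list alone) with 0 falling (median 0.24, camera adjusted p = 3.15e-05; adjusted p = 0.473 with an estimated correlation). RPS9, RPS5, RPS2 and RPLP1 rose by 0.52 ± 0.08, 0.44 ± 0.07, 0.42 ± 0.07 and 0.37 ± 0.06, and many pseudogenes can share their reads. The 15 measured replication-dependent histone genes had 8 that rose and 0 that fell (1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0200; adjusted p = 0.293 with an estimated correlation). Their mRNAs lack poly(A) tails and are poorly captured by such libraries. HIST1H1C rose from 751 ± 42.2 to 1140 ± 123, HIST1H1D from 94.5 ± 8.76 to 241 ± 44.8, HIST1H1E by 1.37 ± 0.25 and HIST2H2AC by 0.73 ± 0.18. The histone call ended without CANN14 replicate 4 (adjusted p = 0.0664) and with a mean of at least 50 normalized counts (adjusted p = 0.273). Without CANN14 replicate 4 or 5, 14 were measured, while 15 stayed measured whichever DMSO replicate was left out. As in the NF-kB list, a member thus passed the filter only through the CANN14 libraries, which favours rises.

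Cell division genes fell. Of 28 mitosis genes 26 fell and UBE2C rose (median -0.50, camera adjusted p = 3.67e-10; adjusted p = 0.293 with an estimated correlation). The mitotic kinesin gene KIF20A fell from 7469 ± 438 to 4093 ± 240 normalized counts, DLGAP5 by 0.78 ± 0.06 on the log2 scale, the cyclin gene CCNB2 by 0.65 ± 0.06 and HMMR by 0.65 ± 0.06. MKI67, the proliferation marker Ki-67, fell from 24723 ± 1498 to 16145 ± 664, and CDKN1A, the cell cycle inhibitor p21, rose from 7579 ± 123 to 12675 ± 1242. Of 34 genes of DNA replication and S phase 22 fell and 6 rose (median -0.24, camera adjusted p = 0.00110; adjusted p = 0.293 with an estimated correlation). UHRF1, RRM2 and MCM3 fell by 0.81 ± 0.07, 0.62 ± 0.06 and 0.61 ± 0.06, whereas the replication licensing factor gene CDT1 rose by 0.65 ± 0.06.

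The type I interferon list fell in 16 of 22 cases (median -0.40, camera adjusted p = 0.00110; adjusted p = 0.293 with an estimated correlation). The antiviral genes OAS3, MX1, IFI6 and IFIT1 fell by 0.87 ± 0.06, 0.81 ± 0.10, 0.77 ± 0.07 and 0.67 ± 0.09, while IRF7, HERC5, IFIT2 and IFIT3 rose. Cholesterol synthesis and uptake genes fell in 14 of 26 cases (15 adjusted over the list alone), and NPC1L1 and SREBF2 rose (median -0.21, camera adjusted p = 0.00484; adjusted p = 0.459 with an estimated correlation). The pathway enzyme genes IDI1, TM7SF2, LSS and HMGCS1 fell by 0.60 ± 0.06, 0.53 ± 0.06, 0.44 ± 0.06 and 0.24 ± 0.06, and the sterol-regulated INSIG1 by 0.48 ± 0.06. Of 13 mRNAs encoded by the mitochondrial genome 12 fell and 0 rose, MT-ND6 being the other (median -0.41, camera adjusted p = 5.59e-05; adjusted p = 0.420 with an estimated correlation). MT-CO3, a subunit of cytochrome c oxidase, fell from 221784 ± 16129 to 141094 ± 5456, and MT-ATP8, MT-ATP6 and MT-ND3 fell by 0.65 ± 0.07, 0.53 ± 0.09 and 0.37 ± 0.06. In the same libraries both mitochondrial rRNAs, looked at after the data were seen, rose, MT-RNR2 from 661870 ± 42683 to 1693974 ± 230872 normalized counts and MT-RNR1 from 102104 ± 5047 to 218654 ± 20223. Whether poly(A) capture or RNA quality differed between groups was not tested. The directions of the ribosomal, histone and mitochondrial lists were the same with total-count scaling on log2(CPM + 1), with medians of 0.17, 0.12 and -0.48.

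**Figure D3:**
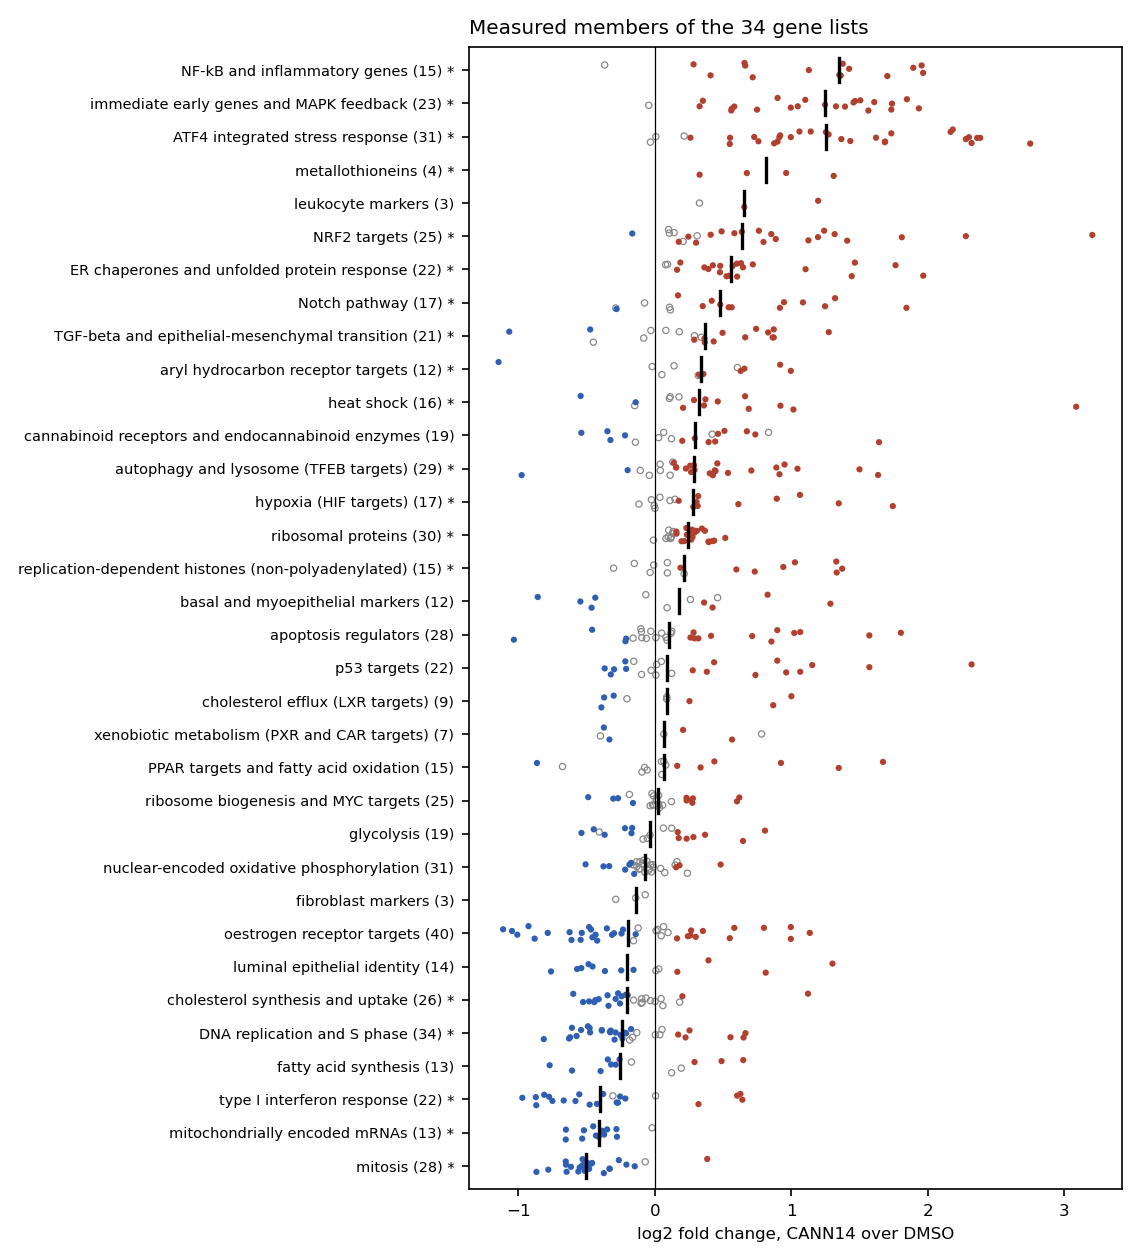
Log2 fold change of CANN14 over DMSO (horizontal axis) of each measured member of the 34 lists (vertical axis, number measured in parentheses), sorted by the median, which is the black bar. Filled red and blue points are members that rose or fell, open points are members not called, and a star marks the 19 lists called by camera with the preset correlation. The mitosis list has a median of -0.50 and the ATF4 list one of 1.25.

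The other 15 lists did not pass camera. Oestrogen receptor targets moved both ways, with 21 of 40 falling and 12 rising (median -0.19, camera adjusted p = 0.117). GREB1, an early target of the receptor, fell from 116109 ± 2245 to 80247 ± 4850 normalized counts and the chemokine gene CXCL12 fell by 1.01 ± 0.07, while the growth factor gene AREG rose by 1.14 ± 0.06 and MYC from 2282 ± 23.1 to 4567 ± 439 normalized counts. SLC7A5 stands in this list too. Of 14 luminal identity genes 8 fell and 4 rose (camera adjusted p = 0.237). ESR1 and MUC1 (-0.46 ± 0.06) fell, and ELF3, CLDN4, CLDN3 and TFAP2C rose, ELF3 by 1.30 ± 0.06 and CLDN4 by 0.81 ± 0.06. Basal and myoepithelial markers had 4 of 12 rising (5 adjusted over the list alone) and 4 falling (camera adjusted p = 0.650). KRT17 rose by 1.29 ± 0.10, EGFR by 0.83 ± 0.09 and CD44 by 0.42 ± 0.05, KRT16 also rose, and CAV1, CAV2, KRT15 and KRT6A fell, CAV1 by 0.86 ± 0.06.

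Of 22 p53 targets 10 rose and 5, RRM2B, ZMAT3, TP53I3, SESN1 and FDXR, fell (median 0.09, mean 0.38, camera adjusted p = 0.0760). Total-count scaling in either unit gave 10 rising and 7 falling in this list, with a median of 0.02. Of 28 apoptosis regulators 12 rose and 4, BCL2, BIRC5, CFLAR and CASP8, fell (median 0.10, camera adjusted p = 0.0760), against 10 rising and 7 falling with total-count scaling in either unit. Both lists passed without CANN14 replicate 6, with adjusted p of 0.0393 and 0.0479, and the p53 list also with total-count scaling on log2(CPM + 1) (0.0481), but not with total counts scaled to the mean library total (0.0804). None of these calls held with an estimated correlation (adjusted p = 0.422 and 0.388 without that replicate, and 0.285 on log2(CPM + 1)). The pro-apoptotic BH3-only genes HRK, BBC3 and PMAIP1 rose by 1.80 ± 0.13, 1.57 ± 0.07 and 1.07 ± 0.07, the nuclease gene AEN by 0.96 ± 0.07 and the death receptor gene TNFRSF10B by 0.90 ± 0.07. Of 19 measured cannabinoid receptors and endocannabinoid enzymes 9 rose and 4, NAPEPLD, NAAA, TRPV4 and FAAH, fell (median 0.29, camera adjusted p = 0.0896; 0.0453 with total counts scaled to the mean library total, where the estimated correlation gave 0.240). Without CANN14 replicate 4 or 5, 17 were measured, 7 rose and 4 fell, with medians of 0.17 and 0.24. As in the NF-kB list, some members passed the filter only through the CANN14 libraries. On log2(CPM + 1) 8 rose and 4 fell, with a median of 0.15. NAPEPLD, which makes anandamide, fell by 0.54 ± 0.07. The channel gene TRPV3, the lipase gene DAGLB and the nuclear receptor gene PPARG rose by 0.74 ± 0.09, 0.44 ± 0.06 and 0.51 ± 0.08.

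Fatty acid synthesis genes fell in 7 of 13 cases (8 adjusted over the list alone), and FADS1, ME1 and FADS2 rose (median -0.26, camera adjusted p = 0.176). FASN, fatty acid synthase, fell from 32509 ± 715 to 19062 ± 551 normalized counts and the elongase gene ELOVL6 by 0.61 ± 0.06, while the desaturase gene FADS1 rose by 0.65 ± 0.07 and ME1 by 0.49 ± 0.06. In the PPAR and fatty acid oxidation list 6 of 15 rose and CD36 fell (camera adjusted p = 0.170). With total-count scaling 5 rose and 3 fell on log2(CPM + 1), and 5 rose and 2 fell with total counts scaled to the mean library total. The lipid droplet gene PLIN2 rose from 212 ± 5.12 to 699 ± 230, ANGPTL4 by 1.35 ± 0.14 and PDK4 by 0.92 ± 0.10, and the fatty acid translocase gene CD36 fell by 0.86 ± 0.10. Cholesterol efflux genes had 3 of 9 rising, APOE (79.6 ± 6.50 to 160 ± 14.5 normalized counts), PLTP (0.87 ± 0.21) and ABCG1, and 3 falling, SREBF1 (-0.37 ± 0.06), ABCA1 (-0.39 ± 0.08) and SMPDL3A (camera adjusted p = 0.935). Glycolysis genes had 7 of 19 rising and 6 falling (median -0.03, mean 0.02, camera adjusted p = 0.908), with ENO2 (0.81 ± 0.07) and HK2 (0.65 ± 0.07) among the first and LDHA (-0.45 ± 0.06) and PGK1 (-0.37 ± 0.06) among the second. The balance depended on the scaling, with ENO2, HK2, PFKP and ALDOA rising and 7 falling on log2(CPM + 1). Nuclear-encoded oxidative phosphorylation genes had 3 of 31 rising, NDUFV2, COX5A and CYC1, and 7 falling (2 and 5 adjusted over the list alone; camera adjusted p = 0.197). With total-count scaling on log2(CPM + 1), NDUFV2 alone rose and 15 fell (median -0.14, camera adjusted p = 0.0695). SDHC, COX6C, ATP5A1 and SDHA fell by 0.51 ± 0.08, 0.38 ± 0.06, 0.33 ± 0.06 and 0.19 ± 0.05, and the SDHA call ended without DMSO replicate 3. Ribosome biogenesis and MYC target genes had 7 of 25 rising and 4 falling (camera adjusted p = 0.628). RRP12 and GNL3 rose by 0.62 ± 0.07 and 0.60 ± 0.07, and POLR1A, UTP20, EBNA1BP2 and BOP1 fell, POLR1A by 0.49 ± 0.06 and UTP20 by 0.30 ± 0.06. In the list of PXR and CAR targets 2 of 7 rose (3 adjusted over the list alone), ALAS1 (0.57 ± 0.08) and POR (0.21 ± 0.05), and 2 fell, CYP3A5 (-0.33 ± 0.08) and CYP2J2 (-0.37 ± 0.10), with a camera adjusted p of 0.935.

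Most markers of other cell types lay below the filter on low counts. Of 11 fibroblast markers 3 were measured and 0 passed, the log2 changes being -0.29 ± 0.12 for COL3A1, -0.14 ± 0.11 for FBLN1 and -0.07 ± 0.07 for COL1A1 (camera adjusted p = 0.309). COL3A1 passed without CANN14 replicate 4 and with total-count scaling in either unit. Of 12 leukocyte markers 3 were measured. CD14 rose from 16.1 ± 3.34 to 39.0 ± 12.8 normalized counts and CSF1R from 47.5 ± 8.04 to 75.4 ± 11.8, and LYZ stood at 14.0 ± 2.70 and 18.2 ± 5.73 (camera adjusted p = 0.125). Some markers below the filter stood apart in 1 library and were named after their values were seen. In CANN14 replicate 5, TYROBP had 48.8 normalized counts, against at most 1.34 elsewhere, and DCN 23.9, against at most 14.9. PTPRC, LUM and CD3E had 11.0, 6.44 and 5.52 normalized counts there. In DMSO replicate 2, DCN and CD163 each had 14.9 normalized counts, where the other DMSO replicates had at most 2.95 and 4.72.

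Gene classes differed in balance. Of 14617 protein-coding genes 4271 rose and 3369 fell, with a median log2 change of 0.03. Of 1496 lincRNA genes 128 rose and 292 fell (median -0.16), and of 1656 antisense genes 142 rose and 288 fell (median -0.13). Processed pseudogenes (42 of 425 rose and 51 fell, median -0.15) and sense-intronic genes (17 of 274 rose and 44 fell, median -0.13) lay as low. Without strand, reads of an antisense gene cannot be told from those of the gene it overlaps.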

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

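The count of changed genes lay between 6860 (adjusted p under 0.01) and 9442 (total-count scaling on log2(CPM + 1)) in every alternative run, against 9036. Leaving out 1 replicate gave 7619 to 8684 changed genes, 800 to 1058 genes changed at least 2-fold and 18 to 21 changed lists. Without CANN14 replicate 5 the 2-fold count was 800, against 988 to 1058 without any other replicate. The 2-fold count, 1049 in the report, moved to 285 with total-count scaling on log2(CPM + 1), 460 with a mean of at least 50 normalized counts, 629 with a pseudocount of 8 and 504 in the authors' deposited table. The alternative on log2(CPM + 1) changed the scaling and the unit at once. Total counts scaled to the mean library total, added after the data were seen to keep the unit, gave 9355 changed genes, 1065 changed at least 2-fold and 20 lists. The lower count of 285 thus came with the unit, while the share of rising genes among calls fell from 52.5% to 41.5% on log2(CPM + 1) and to 41.6% with the unit kept. The stricter filter tests fewer genes. The authors' table counts on the authors' own log2 changes, which were 2.39 for HSPA6 and 2.35 for SLC3A2, against 3.09 and 2.38 here. Its 504 is thus not a like count, and why the log2 changes differ was not tested. limma's voom on the recovered reads, added after the data were seen, called 9073 genes, 8931 of them shared with the 9036. The authors' table called 7440, of which 7372 were shared, all in the same direction.

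Of the 19 list calls, 0 held in camera with an estimated correlation, with adjusted p from 0.293 to 0.528. The estimates rest on 4 residual degrees of freedom. fry, which asks whether the genes of a list move one way on balance and does not set them against other genes, called 27 lists. Of the 153 named genes, none changed direction in any alternative. COL3A1 came to pass without CANN14 replicate 4 and with total-count scaling in either unit, and SDHA no longer passed without DMSO replicate 3. The replication-dependent histones lost their call with a mean of at least 50 normalized counts (0.273) and without CANN14 replicate 4 (0.0664). The p53 targets came to pass on log2(CPM + 1) (0.0481) and without CANN14 replicate 6 (0.0393), the apoptosis regulators without that replicate (0.0479), and the cannabinoid list with total counts scaled to the mean library total (0.0453). With an estimated correlation these were 0.285, 0.422, 0.388 and 0.240. Counts of members near the threshold varied, with 4 to 7 glycolysis genes rising and 4 to 8 falling. No paired analysis was possible because the labels do not say which replicates, if any, belong together. The columns are numbered 1 to 3 in DMSO and 4 to 6 in CANN14, which does not settle it. The count test that the design asked for on recovered reads was not run, although these reads came out whole. In the simulated data 26 of 50 genes changed 1.25-fold were called, so small changes can be missed with 3 replicates. A far smaller share of genes was changed there than the 45.7% of tested genes called here, so the simulated rates do not carry over.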

Other observations

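Tests chosen only after the result was seen were those of the gene lists in the next paragraphs, of abundant transcripts and markers of other cell types in DMSO replicate 2, of genes far above the rest in 1 library, of untreated RNA in CANN14 replicates, and of other splits of the libraries.

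Genes of the circadian clock rose together. Of 20 measured members 17 rose and 0 fell, with a median log2 change of 0.71 (camera adjusted p = 4.53e-08 over 9 lists chosen after the data were seen; adjusted p = 0.318 with an estimated correlation). They included the repressor genes NR1D1 (1.98 ± 0.10, SE), NFIL3 (1.76 ± 0.09), PER1 (1.46 ± 0.08) and BHLHE40 (1.32 ± 0.07), while CLOCK stood at -0.02 ± 0.06. With total-count scaling on log2(CPM + 1) 17 rose as well. AXIN2, a feedback target of Wnt signalling, rose from 88.4 ± 10.6 to 377 ± 38.3 normalized counts (SD, n = 3), although the 12 measured Wnt feedback genes did not pass as a list (camera adjusted p = 0.212). Of them 6 rose and 3, APCDD1, DKK1 and RNF43, fell, and 4 to 6 rose with 1 replicate left out. Their median was 0.29, against 0.16 on log2(CPM + 1), where 4 rose and 4 fell.

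Cytosolic aminoacyl-tRNA synthetase genes rose in 13 of 20 cases and HARS fell (median 0.33, camera adjusted p = 2.73e-04; adjusted p = 0.489 with an estimated correlation). AARS rose by 1.27 ± 0.07 and YARS by 1.15 ± 0.07. AARS, GARS, SARS and WARS also belong to the ATF4 list, so this list in part restates that result. Of 17 mitochondrial synthetase genes 6 fell, LARS2 by 0.51 ± 0.08, and WARS2 rose (camera adjusted p = 0.212); the difference between both lists was not tested. Amino acid transporter genes rose in 14 of 23 cases and fell in 5, SLC38A1, SLC7A8, SLC38A10, SLC7A2 and SLC1A1 (camera adjusted p = 0.00586; adjusted p = 0.318 with an estimated correlation). Of the transporter genes, SLC3A2, SLC7A11, SLC7A5 and SLC38A2 also belong to the ATF4 list. Both mitochondrial rRNAs rose while 12 of 13 mitochondrial mRNAs fell. MT-RNR2 rose from 661870 ± 42683 to 1693974 ± 230872 normalized counts, and MT-RNR1 from 102104 ± 5047 to 218654 ± 20223. These rRNAs are poorly captured by poly(A) selection, as are the replication-dependent histone mRNAs, of which 8 of 15 rose, and whether capture differed between groups was not tested. Both measured UGT2B genes fell, UGT2B15 and UGT2B17 (-1.23 ± 0.30). They were looked at together because UGT2B15 had fallen, and being near-identical they can share reads, so they do not count as separate falls. Of 31 proteasome subunits 1 rose, PSMD11, and 6 fell, of which PSMA4, PSMD12, PSMB1 and PSMA3 passed when adjusted over the list alone (camera adjusted p = 0.212). Leaving out 1 replicate gave 1 to 8 falling, while with total-count scaling on log2(CPM + 1) 12 fell and the list passed (adjusted p = 0.0406; adjusted p = 0.488 with an estimated correlation). The 12 tubulins (6 rose and 4, TUBA1B, TUBB4B, TUBA1A and TUBG1, fell, adjusted p = 0.398) did not pass camera.

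DMSO replicate 2 detected 4037 genes that no other library did, 5.29 times the next highest number, and 4.10 times after all libraries were thinned to the smallest total. Of these genes 68.1% had a single read, and the 1% most-hit held 4.0% of the reads. RNA of another cell type or library stays open, since that share leaves out transcripts also found elsewhere and 11 of 15 fibroblast and leukocyte markers below the filter were higher here than in DMSO replicates 1 and 3 (binomial p = 0.00181), as reads in silent genes from any source would make them. Genes silent elsewhere had 0.74 times the rate of reads per kb inside an expressed gene as outside one (95% interval 0.67 to 0.82). They thus showed no excess inside expressed genes, where unspliced RNA of those genes would raise the rate. However, genes that took up such reads in any other library were left out as not silent, so this ratio cannot exclude unspliced RNA. Genomic DNA covering all gene classes evenly would give similar rates in each class. LincRNA (0.696 reads per kb) and protein-coding genes (0.326) of 1000 to 2000 bp differed 2.13-fold, which speaks against it. That gap is close to the bound of 2 set in advance, and unequal mapping of these classes was not measured. The choice of genes silent elsewhere also shapes it. The share of silent genes with a read rose with exonic length, as even coverage would make it. It was 26.1% at 300 to 1000 bp, 37.8% at 1000 to 2000 bp and 47.4% at 2000 to 4000 bp. Genomic DNA thus stays open. No biological explanation was tested, and without this replicate 7619 genes were called.

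CANN14 replicate 5 showed larger changes than replicates 4 and 6. Over genes changed by at least 0.5 on the log2 scale in the mean of the other 2, the slope of its changes on theirs was 1.19 ± 0.0065 (bootstrap SE over genes), against 0.87 for replicate 4 and 0.84 for replicate 6. Sequencing depth does not account for it, since the slope was 1.19 after thinning to the smallest total. A share of untreated RNA in replicates 4 and 6 stays open, since it requires their changes to be the same fraction of those of replicate 5 in rising and falling genes, and that gap was -0.138 and -0.139 as deposited but -0.003 and -0.008 with replicate 5 scaled down by 5%, and -0.259 in both with it scaled up by 5%. A stronger exposure in replicate 5 was not tested and stays open as well.

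CANN14 replicate 5 also had 13 genes with at least 10 normalized counts there and at least 8 times the highest other library plus 1, against 1 gene, PCDH15, in DMSO replicate 2 and 0 in each other library. Among them were CYP11A1 (86.5 normalized counts, at most 4.03 elsewhere) and HSD3B2 (71.8, at most 4.37), genes of steroid hormone synthesis, and SRGN (70.8, at most 2.95) and TYROBP (48.8, at most 1.34), which leukocytes express. They were named after their values were seen, and none passed the filter on low counts. RNA of other cells or libraries in that replicate was not tested and stays open.

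LincRNA and antisense genes lay lower than protein-coding genes in CANN14, with a median log2 change of -0.14 against 0.03, as did processed pseudogenes (-0.15) and sense-intronic genes (-0.13). The extra genes of DMSO replicate 2 were at 0 in every other library, so none passed the filter or entered this gap. Excess reads of that replicate in tested genes do not account for the gap of 0.17. It was 0.174 ± 0.0105 (bootstrap SE) without that replicate. Bootstrap errors here are over genes and leave out the spread between libraries. Against the mean of all 3 DMSO replicates, the gap was 0.152, 0.257 and 0.069 in CANN14 replicates 4, 5 and 6. Low expression does not either, since protein-coding genes matched on mean count still lay 0.144 ± 0.0141 higher. An effect of the extract on non-coding transcripts was not tested and stays open, as do genes that overlap without strand.

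With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 9036 changed genes, 1049 changed at least 2-fold and 19 changed lists. The highest of the other splits, which mix both groups, gave 0, 0 and 13. Mixing puts the difference between CANN14 and DMSO inside the compared groups. That all but fixes the 0 called genes in advance, so the gene counts say nothing about chance. Camera at the preset correlation still called 4 to 13 lists in each mixed split, where no gene was called. These splits keep part of the difference between groups, so they give no chance level for the 19 lists either.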
